A study of Mus musculus with 21 samples.

How the data were processed

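Chromosome conformation capture on chip combined with sequencing (4C-seq) reads out which parts of the genome lie near 1 chosen fragment, the viewpoint, in the nuclei of a cell population. Per the labels' protocols, mouse cells were fixed with 2% formaldehyde for 10 minutes, chromatin was cut with a first restriction enzyme and ligated, cut again with a second enzyme and ligated again, and the partners of the viewpoint were amplified by inverse PCR and sequenced. The 21 libraries covered 11 viewpoints at 4 loci in fetal liver (7 libraries), fetal brain (6), embryonic stem (ES) cells (4) and adult thymus (4). Each combination of viewpoint, tissue, enzyme pair and template amount was its own group of 1 library, so there were no replicates, no test was run and no p-value was computed. The titles of the liver libraries of the Hba-a1 promoter (full template), the Hbb-b1 promoter, HS-2 and 3' HS-1 carry longer numbers than those of their brain partners. Whether these liver libraries pool several runs is not given in the sources used here, so a difference in make-up between the tissues is possible.

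The deposited files hold a signal, in steps of 1000 bp, that the authors had smoothed over 48 running windows of 2 to 49 kb. The files have no header, and the window sizes were read from the unfilled positions at both ends of each column. Each window has 3 columns, a middle value with a higher and a lower one, and this order held at 100% of positions in every library. The file names describe the values as normalized medians, and the quantile levels of the outer columns are not given in the sources used here. In every library some middle values were exactly 1, all within 4.75 kb of the viewpoint, so signals were treated as relative to the level at the viewpoint. Coordinates are in mm9, per the submitters' processing notes. The aligner, the filters and the number of reads are not given in the sources used here, so sequencing depth is unknown and no counting interval was computed.

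The smoothing window of 5 kb was the main scale. The viewpoint was placed at the position of the highest signal, as the median over the libraries of that viewpoint, and single libraries lay at most 3 kb from it. Positions within 10 kb of the viewpoint were left out. Observed over expected (O/E) was the mean signal within 5 kb of a target, divided by the mean expected at those distances from a monotone decay fitted to the same library over both sides of the viewpoint. A pseudocount of 10% of the library's mean beyond 10 kb was added to both. Its percentile was taken among positions of the same library at 0.5 to 2 times the distance of the target. Relative signal is the signal divided by the library's mean beyond 10 kb, and positions under 1e-09 were counted as empty.

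Libraries were compared by the difference of log2 O/E. The yardstick for such differences was fixed before the data were examined as the SD over positions of the log2 ratio between the full and 1/16 template libraries of the Hba-a1 promoter in liver, each scaled to its mean, which came to 1.04. It comes from 1 viewpoint and 1 technical pair, so it measures neither biological spread nor the spread of other viewpoints. It is taken on signal at single positions with the decay left in, whereas the differences are of O/E averaged over targets. A difference within it is therefore not shown to lie within the technical spread of O/E. The SD of the 5 kb window was held fixed for all settings, although wider averaging lowers noise too. Recomputed after the data were seen, it was 1.56 at 2 kb, 0.90 at 10 kb and 0.92 at 20 kb. By these, 1, 6 and 3 of the 14 differences between tissues were higher beyond the SD, and 1, 1 and 2 lower. A narrower yardstick, the SD of the same pair's difference of log2 O/E over the target width, was added after the data were seen and came to 0.45. Positions on grids that differ between libraries were matched within 500 bp. Libraries made with different enzymes or from neighbouring viewpoints were compared in bins of 5 kb. Correlations are across positions or bins, which are not independent replicates, and their 95% intervals come from 1000 bootstrap draws of 50 kb blocks. Pairs of the Hba-a1 promoter had 7 blocks, the Oct4 pair 8 and the Satb1 pairs 26. With so few blocks the intervals are rough, most of all at the Hba-a1 and Oct4 promoters.

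The rule for named positions was also fixed before the data were examined. It takes all viewpoints as targets of the other viewpoints of their locus, up to 5 maxima of O/E per library at least 20 kb apart with signal in the library's top 25%, and up to 5 positions per direction with the largest difference between tissues. Naming only maxima with O/E above 1 was decided after the data were seen, as were the limit for empty positions, the bootstrap intervals, the shares of signal per side, the commonest values and the sites recurring across libraries. HS elements with no viewpoint of their own were placed by the distances in their names, relative to HS-26. Lists of neighbouring genes had been fixed for use with an mm9 annotation and were not used here. A gene table of GRCm38.p6 gave only chromosomes, names and the order of neighbouring genes.

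The procedure was tested on 100 simulated profiles per setting with 1 planted contact each. For a planted log2 excess of 2, the median log2 O/E was 1.03 on the Hba-a1 promoter's grid of 346 positions and 1.24 on the Satb1 promoter's grid of 1296 positions. The contact was among the maxima in 98% and 72% of those simulations. For a planted log2 excess of 1 these shares were 62% and 49%. The simulated decay was the same on both sides, with no empty positions and no recurring values, unlike many of the libraries. No profile without a contact was simulated, so the share found without one is unknown. In these simulations O/E understated a contact. In the libraries it depended on the decay, and log2 O/E of the Hba-a1 promoter at HS-26 in liver ran from 0.86 to 4.06 over the settings, around 1.68. Alternatives were smoothing windows of 2, 10 and 20 kb, targets reaching 2.5 and 10 kb to either side, a decay fitted on the target's side alone, a power-law decay, no decay, a pseudocount of 1%, the 1/16 template library, positions beyond 50 kb, bins of 10 kb and other limits for maxima. Their use for maxima, for HS elements placed by name and for positions with the largest tissue differences was added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.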

Results

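Contacts of 11 viewpoints at 4 mouse loci were measured by 4C-seq in 21 libraries. At the alpha-globin locus on chromosome 11, 5 libraries looked out from the Hba-a1 promoter and from HS-26, a hypersensitive site known as the major alpha-globin enhancer. At the beta-globin locus on chromosome 7, 7 libraries used the Hbb-b1 promoter, HS-2 of the locus control region, and the flanking sites 3' HS-1 and HS-62. Chromosome 17 held the promoter of Oct4 (Pou5f1), a transcription factor of pluripotent cells, with 2 libraries, and Satb1, a chromatin organizer highly expressed in thymocytes, with 7. There were no replicates. Fetal tissues were taken at 14.5 days post coitum.

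Sequencing depth is unknown, and the fill of the profiles differed between libraries. The share of empty positions beyond 10 kb ran from 0.531% to 51.2%. It was 21.2% for the Hba-a1 promoter, 24.1% for the Hbb-b1 promoter and 51.2% for HS-2 in liver, against 0.531%, 6.37% and 6.90% in brain. For HS-26 it was 0.613% in both tissues, yet 38.7% of its liver positions held the commonest value, against 6.13% in brain. For 3' HS-1 the empty share was 3.99% in liver and 6.65% in brain. Several profiles were flat over long stretches at 1 recurring value. In the NlaIII/Csp6I library of the Oct4 promoter, 43.6% of positions held the commonest value, and in the 1/16 template library of the Hba-a1 promoter 43.8% did. Low values in such stretches have no order.

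The alpha-globin comparison asks whether a globin promoter and its enhancer meet more often in fetal liver, the erythroid tissue of the fetus, than in fetal brain, where globin genes are silent. From the Hba-a1 promoter, HS-26 (chromosome 11, 32144250 to 32154250, mm9) stood 3.20-fold above expectation in liver and 1.31-fold in brain. The liver value was at percentile 100 of distance-matched positions and the brain value at percentile 82.4. In relative signal, HS-26 reached 13.9 times the library mean in liver and 2.94 times in brain. Looking back from HS-26, the Hba-a1 promoter (32179894 to 32189894) stood at 2.30 in liver and 1.31 in brain, at percentiles 88.8 and 99.1.

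The difference of log2 O/E between liver and brain was 1.29 from the Hba-a1 promoter to HS-26, beyond the template pair's SD of 1.04. It was 0.81 in the reverse direction, within that SD and beyond the narrower yardstick of 0.45 added after the data were seen. The liver signal at HS-26 averaged 0.574, between mean lower and higher window values of 0.135 and 1.51, while the brain signal averaged 0.0844, between 0.0230 and 0.160. With the decay fitted on the target's side alone the promoter's difference was 0.61, and with the 1/16 template library 0.94, both within the SD. It stayed beyond the SD in 7 of 10 other settings. The gene table lists HS-26 as another name of Nprl3, which with Hba-x precedes Hba-a1.

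Other elements of the alpha-globin cluster, placed by the distances in their names, were higher in liver in all 6 comparisons, and 1 exceeded the template pair's SD. From the Hba-a1 promoter, HS-31 stood at 2.67 in liver and 1.27 in brain, a log2 difference of 1.07 that fell to 0.93, within the SD, with the 1/16 template library, and HS-21 differed by 0.98. Both elements are placed 5 kb from HS-26, so their windows overlap its window. The windows of HS-12 and HS-8 overlap each other. HS-12 and HS-8 differed by 0.17 and 0.12 from the promoter. From HS-26 they differed by 0.61 and 0.96.

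Highest O/E from the Hba-a1 promoter in liver was at 32149000, 0.25 kb from the HS-26 viewpoint, followed by positions at 32.113 Mb (O/E 2.36) and 32.170 Mb (1.20). The 1/16 template and brain libraries each had maxima within 10 kb of these 3 positions. The maximum from HS-26 in liver was at 32.191 Mb, 6.11 kb beyond the Hba-a1 promoter, with O/E 3.32. Liver exceeded brain most at 32.150 Mb from the Hba-a1 promoter, by 1.27, and from HS-26 at 32.192 Mb, 7.11 kb beyond the Hba-a1 promoter, by 1.50, beyond the SD. With the decay fitted on their side alone these were 0.59 and 0.85, within it. Brain exceeded liver most at 32.211 Mb from the Hba-a1 promoter, where O/E was 0.936 in brain and 0.0984 in liver. Relative signals there were 2.22 in brain and 0.330 in liver. With the decay fitted on that side alone the difference of log2 O/E was -0.58, within the SD. Such a decay takes its level from 1 side, so it shrinks a difference shared by the whole side whatever its cause. The same decay left brain above liver beyond the SD at 32.174 Mb from the Hba-a1 promoter (-1.12, then -1.71) and at 32.176 Mb from HS-26 (-0.64, then -1.27). Both lie between the Hba-a1 promoter and HS-26. A monotone decay pools a stretch of low signal with a higher peak beyond it, so positions before the liver peak fall below expectation by construction. Relative signals were 4.76 in brain and 2.14 in liver at the first, and 2.25 and 1.96 at the second. Of the signal beyond 10 kb over distances covered on both sides, 89.7% lay on the HS-26 side of the Hba-a1 promoter in the full liver library, 74.8% in the 1/16 template library and 58.1% in brain, with a reach of 162 kb in the first and 197 kb in the others. For HS-26, 81.1% lay on the promoter's side in liver and 53.2% in brain.

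**Figure D1:**
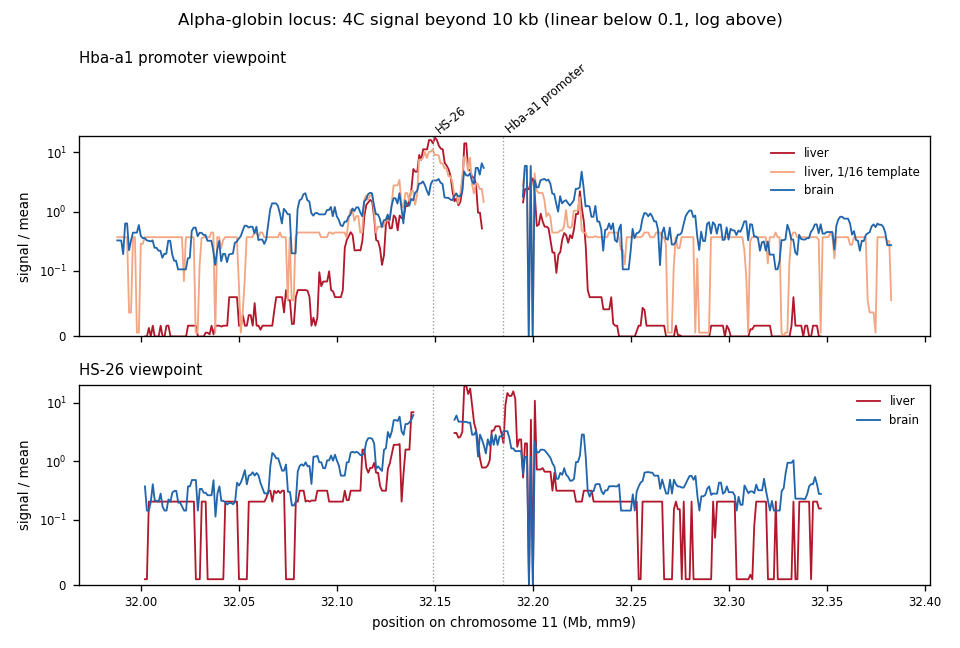
Smoothed 4C signal divided by the library mean beyond 10 kb (vertical axis, linear below 0.1 and logarithmic above) along chromosome 11 (Mb, mm9) for the Hba-a1 promoter and HS-26 viewpoints, 1 line per library, with positions within 10 kb of the viewpoint left out. From the Hba-a1 promoter the liver line reaches its highest region around HS-26, where the mean was 13.9 in liver and 2.94 in brain.

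The beta-globin comparison puts the same question for the Hbb-b1 promoter, the locus control region and the outer sites 3' HS-1 and HS-62, which are known as CTCF-bound sites. Hbb-b1 and HS-2 were higher in liver from both ends. From the Hbb-b1 promoter, HS-2 (chromosome 7, 111001000 to 111011000) stood at O/E 2.83 in liver and 1.08 in brain. From HS-2, the Hbb-b1 promoter (110972000 to 110982000) stood at 2.19 in liver and 0.997 in brain. The log2 differences were 1.39 and 1.14, both beyond the template pair's SD.

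These differences narrowed when the decay was fitted on the target's side alone, to 0.68 from the Hbb-b1 promoter and 0.73 from HS-2, within the SD. They stayed beyond it in 5 of 9 and 6 of 9 other settings. Empty positions made up 24.1% of the Hbb-b1 promoter library and 51.2% of the HS-2 library in liver. In brain these shares were 6.37% and 6.90%. No diluted library was made for these viewpoints, so library fill and the tissue cannot be told apart here either. The liver signal at HS-2 averaged 0.398, between lower and higher window values of 0.0634 and 1.25, and the brain signal averaged 0.0686, between 0.0230 and 0.207.

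Of the 9 pairs of viewpoint and target at this locus, 7 were higher in liver, and 2 of those exceeded the template pair's SD. The pair of Hbb-b1 promoter and 3' HS-1 (110937500 to 110947500) was lower in liver beyond that SD, with O/E 0.208 in liver and 1.03 in brain and a log2 difference of -2.31. Fitting the decay on the target's side alone turned this direction, to 0.60, and a power-law decay left -0.32, within the SD. It stayed lower beyond the SD in 7 of 9 other settings, among them no decay at -1.28. In liver its O/E was at percentile 29.8 of distance-matched positions, and the difference was at percentile 29.8 of the differences at such positions. A deficit of this size was thus not particular to 3' HS-1. The remaining 6 pairs lay within the SD. From HS-2, 3' HS-1 differed by 0.90 and HS-62 (111053000 to 111063000) by -0.63. From 3' HS-1, HS-62 differed by 0.71, the Hbb-b1 promoter by 0.27 and HS-2 by 0.07. From the Hbb-b1 promoter, HS-62 differed by 0.54. The sign turned in other settings for HS-62 from HS-2 (to 0.37) and from the Hbb-b1 promoter (to -1.01), and from 3' HS-1 for HS-2 (to -0.55) and the Hbb-b1 promoter (to -0.14).

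HS-62 was profiled in liver alone, with other enzymes. Its library had O/E 1.95 at 3' HS-1, 115.5 kb away, 1.44 at HS-2 and 1.39 at the Hbb-b1 promoter. With the decay fitted on the target's side alone the latter 2 turned slightly below expectation, with log2 O/E of -0.03 and -0.20, and 3' HS-1 kept 0.24. Its highest position was 110.946 Mb with O/E 2.99, 3.5 kb from the 3' HS-1 viewpoint, followed by 110.864 Mb with 2.77, and the 2 kb window turned this order. From 3' HS-1 in liver the highest position was 111.024 Mb with O/E 3.02, 18 kb beyond HS-2, and 111.054 Mb near HS-62 followed with 1.65. The HS-62 library had a maximum at 111.023 Mb with O/E 1.68, and HS-2 in liver had one at 111.018 Mb with 1.79.

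Liver exceeded brain most at 111.020 Mb from 3' HS-1, where O/E was 2.99 in liver and 1.01 in brain, and at 110.963 Mb from HS-2, where it was 2.04 and 0.676. Brain exceeded liver by more, with a log2 difference of -4.25 at 110.934 Mb from the Hbb-b1 promoter and -3.39 at 111.041 Mb from HS-2. Relative signals at these 4 positions were 4.19, 5.16, 0.159 and 0.150 in liver and 0.879, 0.709, 2.10 and 1.04 in brain. With the decay fitted on the position's side alone the 4 differences of log2 O/E were 0.99, 0.46, -0.36 and -0.99, all within the SD. As that decay shrinks differences shared by a whole side, it does not show them to be absent. With that decay brain was above liver beyond the SD at 110.991 Mb from the Hbb-b1 promoter (-1.60, then -2.09) and at 110.994 Mb from HS-2 (-1.76, then -1.78). The same held at 110.983 Mb from 3' HS-1 (-0.64, then -1.10), 40.5 kb from that viewpoint. These positions lie between their viewpoint and a higher liver peak, where the monotone decay lowers O/E as at the alpha-globin locus. Relative signals there were 4.11, 3.67 and 1.79 in brain and 1.50, 1.44 and 0.960 in liver. From the Hbb-b1 promoter the highest maximum in liver was 111.008 Mb with O/E 2.92, 2 kb from HS-2. The side of the Hbb-b1 promoter that holds HS-2 took 79.1% of the signal in liver and 46.5% in brain. From 3' HS-1, the side that holds the globin genes took 66.1% in liver and 42.4% in brain. The genes that follow Hbb-y in the gene table are olfactory receptor genes, Olfr66 first.

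**Figure D2:**
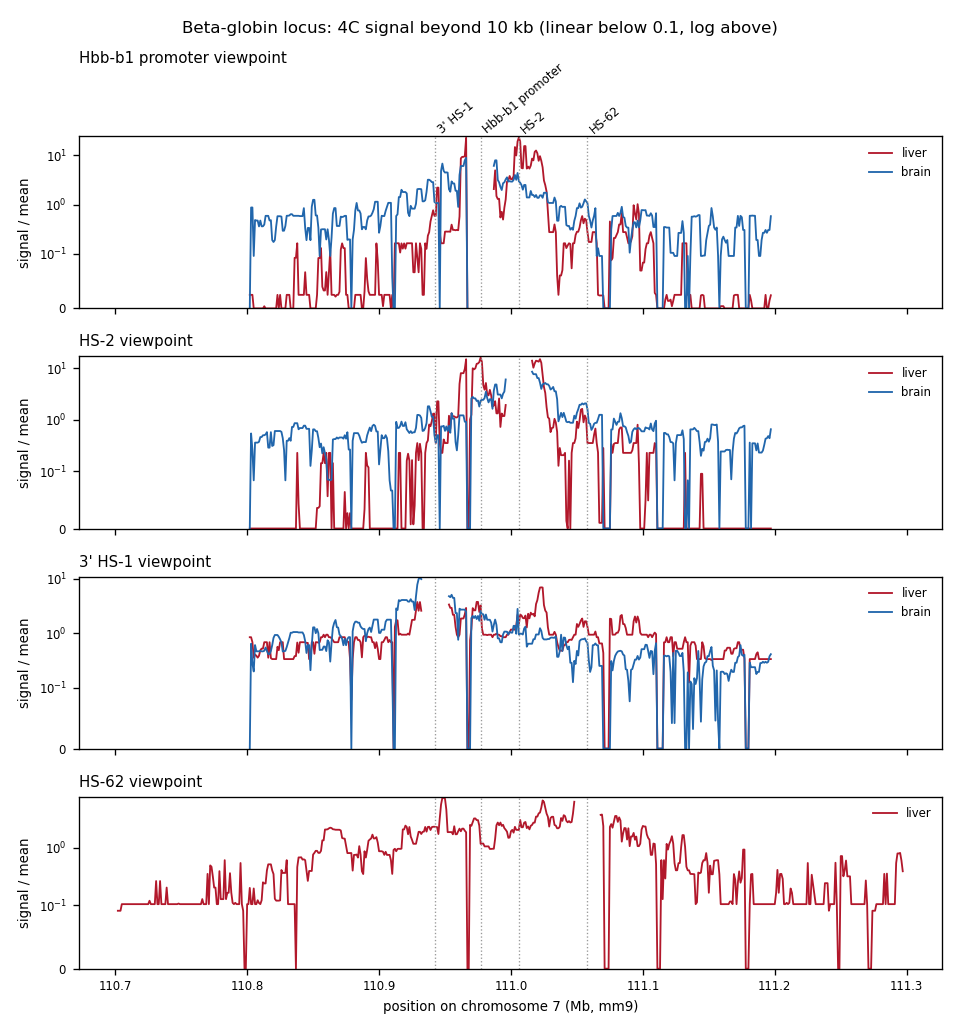
Smoothed 4C signal divided by the library mean beyond 10 kb (vertical axis, linear below 0.1 and logarithmic above) along chromosome 7 (Mb, mm9) for 4 beta-globin viewpoints, 1 line per library. From the Hbb-b1 promoter, HS-2 had a relative signal of 12.3 in liver and 3.00 in brain, and from HS-2 the Hbb-b1 promoter had 9.35 and 2.51.

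Dilution of the template asks how much input a 4C profile needs. The Hba-a1 promoter kept its main contact at 1/16 of the template, with HS-26 at a log2 O/E of 1.32 against 1.68 with full template, and at 8.98 times the library mean against 13.9. All 3 named maxima of the full library had a partner within 10 kb, at 32.147, 32.113 and 32.169 Mb. All 3 also had a partner in the brain library, so shared maxima do not tell this technical pair from a tissue pair. Over 326 positions the SD of the log2 ratio was 1.04 (95% interval 0.76 to 1.21), and 31.9% of positions lay within 2-fold. After division by the expected decay the SD was 0.87, and 79.8% lay within 2-fold. Pearson's r of log2 signal was 0.861 (0.467 to 0.908) and Spearman's rho 0.817 (0.542 to 0.913). For comparison, liver and brain differed from the Hba-a1 promoter with an SD of 1.36 (0.73 to 1.69) and a rho of 0.765 (0.391 to 0.846). The intervals of the technical and the tissue pair overlap, but each rests on 7 blocks and is rough.

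Oct4 was profiled in ES cells with 2 enzyme pairs, which asks whether a contact depends on the fragments cut. Both libraries had strong contacts 21.2 and 27.2 kb to the lower-coordinate side of the Oct4 promoter (chromosome 17, 35639250 to 35649250). With NlaIII/Csp6I the highest maximum was 35.623 Mb with O/E 2.23, and with DpnII/Csp6I 35.617 Mb had 2.17. A second shared site was at 35.576 and 35.572 Mb, with O/E 2.15 and 1.59. The first of these values fell to the expected level with the 20 kb window, at a log2 O/E of -0.000897. These 2 of 5 maxima of the NlaIII/Csp6I library had a partner within 10 kb among the 3 maxima of the DpnII/Csp6I library, whose highest, 35.706 Mb with O/E 2.23, had none.

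Over 76 bins of the Oct4 locus the SD of the log2 ratio was 0.78 (95% interval 0.60 to 0.90), and 82.9% of bins lay within 2-fold. Pearson's r was 0.831 (0.647 to 0.893) and Spearman's rho had an interval of 0.493 to 0.877. After division by the expected decay rho was 0.468, below that interval. In 36 of 396 shared positions both libraries were empty, including 35.538 to 35.552 Mb, 35.584 to 35.597 Mb and 35.616 to 35.617 Mb. The last of these holds the DpnII/Csp6I maximum named above, whose O/E is a mean over 5 kb to either side and so comes from its neighbours. The gene table places H2-Q10 and Tcf19 directly beside Pou5f1.

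Satb1 contacts were compared between thymus, where the gene is highly expressed, and ES cells and fetal brain. The Satb1 promoter (chromosome 17, 51969000 to 51979000) and the viewpoint named -470 kb (52415250 to 52425250) were above expectation in thymus from both ends. In ES cells from both ends, and in brain from the promoter, the only end profiled there, they were near expectation. From the promoter, the -470 kb site stood at O/E 2.01 in thymus, 0.913 in ES cells and 0.855 in brain. From the -470 kb site, the promoter stood at 2.43 in thymus and 0.926 in ES cells. Over other settings log2 O/E in these tissues took both signs, from -2.46 to 0.02 and -0.86 to 0.22 from the promoter in ES cells and brain, and from -1.65 to 0.37 from the -470 kb site in ES cells. Percentiles were 89.4 in thymus and 22.6 in brain from the promoter, and 96.2 in thymus and 49.1 in ES cells from the -470 kb site.

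The log2 differences at these sites were 1.14 for thymus against ES cells and 1.23 against brain from the promoter, which share the thymus library, and 1.39 for thymus against ES cells from the -470 kb site. All 3 exceeded the template pair's SD, and fell within it with the 20 kb window, at 0.78, 1.00 and 0.94, and with targets reaching 10 kb to either side, at 0.87, 0.85 and 0.90. From the promoter they did so with the 10 kb window too, at 0.93 and 1.01. They stayed beyond it in 6, 6 and 7 of 9 other settings. These settings include the decay on the target's side, which hardly acts from the promoter, as the other side ends before 446.25 kb. Against the template pair's SD of the same window, 3 of these differences were beyond it at 10 kb, 2 at 20 kb and 0 at 2 kb. The relative signal at the -470 kb site was 1.48 in thymus and 0.506 in brain. In ES cells it equalled the commonest value of that library, held by 30.1% of positions, so the ES level there is a floor without a rank, and the pseudocount in its O/E of 0.913 is about as large as the signal. The measured distance between both viewpoints was 446.25 kb, against the -470 kb of the label. In the gene table Kcnh8 and Tbc1d5 flank Satb1, with Kcnh8 on the higher-coordinate side, where the -470 kb site lies.

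Further thymus contacts of the Satb1 promoter lay on the same side. Its highest maxima were 52.598 Mb with O/E 5.12, 52.319 Mb with 3.16, 52.019 Mb with 3.06, 52.206 Mb with 3.05 and 52.359 Mb with 2.93. In that library 86.6% of the signal within 272 kb lay on the higher-coordinate side, against 47.8% in ES cells and 50.0% in brain. From the neighbouring thymus viewpoints the share was 60.97% at +1.5 kb and 78.4% at -6 kb. ES cells had their highest maxima at 52.323 Mb with O/E 2.40 and at 51.723 Mb with 2.23, and brain at 52.600 Mb with 2.05 and at 52.213 Mb with 1.56. Thymus exceeded ES cells most at 52.154 Mb, with O/E 1.97 against 0.328, and brain most at 52.319 Mb, with 3.16 against 0.905. At 51.922 Mb thymus stood at 0.0921, ES cells at 0.784 and brain at 0.919, differences of -3.09 and -3.32. These turned to 0.03 and 0.04 with the decay fitted on that side alone, which takes its level from the signal-poor side in thymus. Relative signals there were 0.278 in thymus, 3.90 in ES cells and 2.98 in brain, so the difference in signal remains.

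From the -470 kb site in thymus the highest position was 51.959 Mb with O/E 2.98, followed by 52.042 Mb with 2.81. In ES cells it was 52.577 Mb with 1.97, away from Satb1. Thymus exceeded ES cells most at 51.970 Mb, within 5 kb of the Satb1 promoter, with O/E 2.69 against 0.862. ES cells exceeded thymus most at 52.520 Mb, by a log2 difference of -2.33, next to positions empty in all Satb1 libraries (52.516 to 52.519 Mb). Across 256 bins, Spearman's rho of the Satb1 promoter's signal was 0.568 (95% interval 0.266 to 0.779) between thymus and ES cells and 0.629 (0.380 to 0.792) between thymus and brain. After division by the expected decay these were 0.074 and 0.080.

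**Figure D3:**
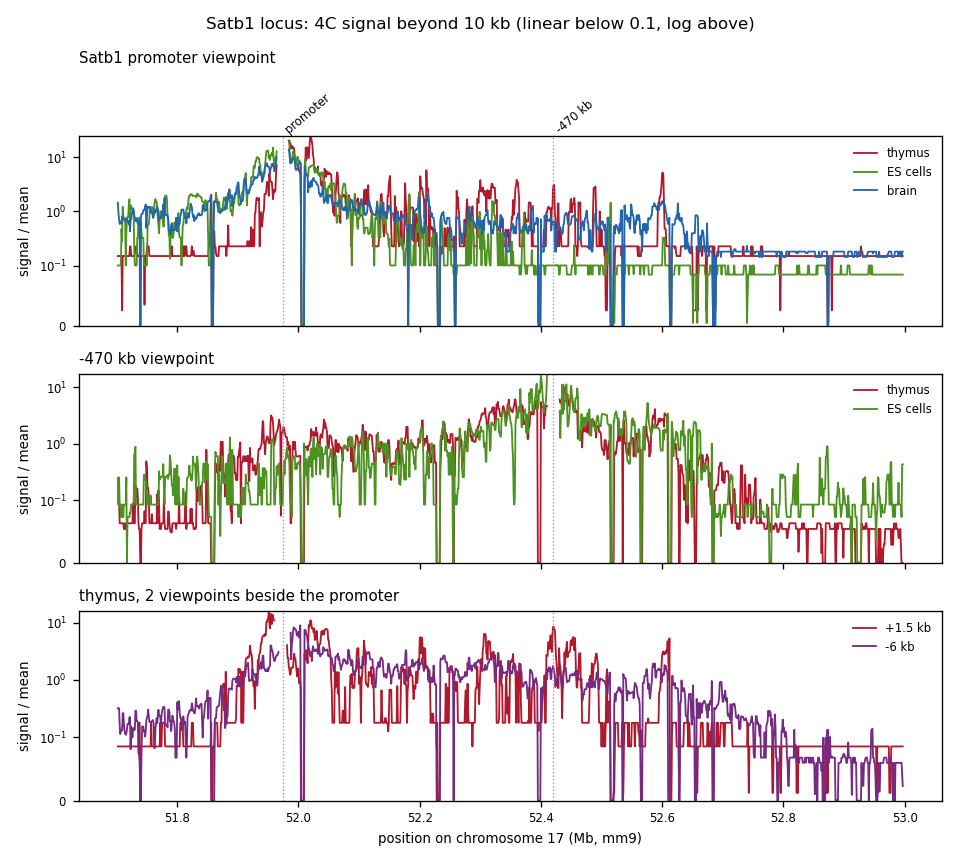
Smoothed 4C signal divided by the library mean beyond 10 kb (vertical axis, linear below 0.1 and logarithmic above) along chromosome 17 (Mb, mm9) for the Satb1 viewpoints, 1 line per library. In thymus the Satb1 promoter had a relative signal of 1.48 at the -470 kb site, and 0.506 in brain.

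The 3 thymus viewpoints near the Satb1 promoter, each with another enzyme pair, show how far neighbouring fragments give the same contacts. The -470 kb site stood at O/E 5.65 from the viewpoint at +1.5 kb, 2.01 from the promoter and 1.20 from the viewpoint at -6 kb. Its percentiles were 99.7, 89.4 and 74.5. From +1.5 kb the highest maximum was 52.418 Mb with O/E 5.71, 2.25 kb from the -470 kb viewpoint, followed by 52.607 Mb with 5.21. From -6 kb the highest was 52.117 Mb with 2.19.

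Profiles of these neighbours were correlated over bins of 5 kb. Spearman's rho was 0.851 (95% interval 0.761 to 0.899) between the promoter and +1.5 kb, 0.870 (0.780 to 0.907) between the promoter and -6 kb, and 0.845 (0.752 to 0.881) between +1.5 kb and -6 kb. The SDs of the log2 ratio were 1.06, 0.99 and 1.17, and 75.7%, 68.2% and 54.7% of bins lay within 2-fold. Division by the expected decay lowered rho to 0.655, 0.693 and 0.540. The promoter shared 3 of its 5 maxima within 10 kb with +1.5 kb and 2 with -6 kb, and the latter 2 viewpoints shared 1.

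**Figure D4:**
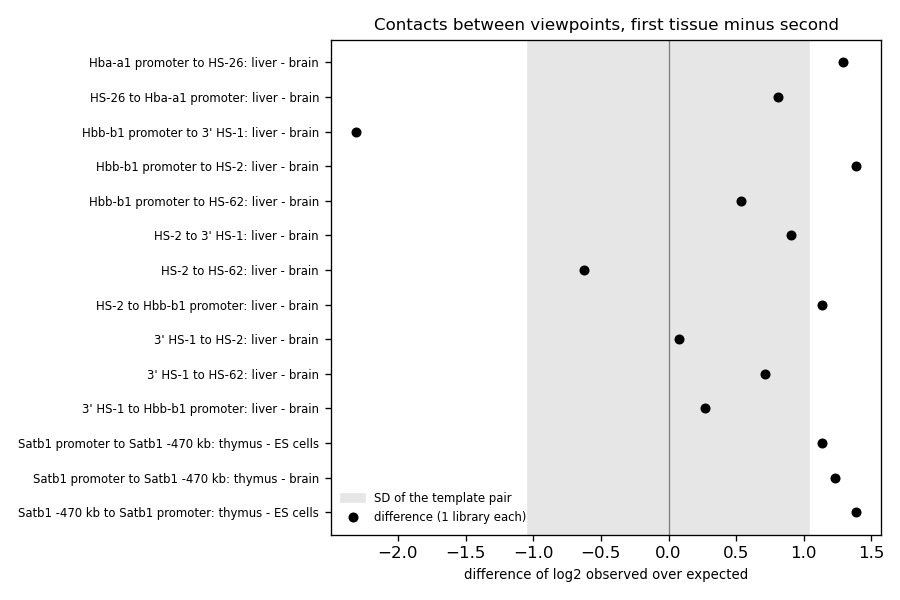
Difference of log2 O/E between the first and second tissue (horizontal axis) for the 14 pairs of viewpoint and target, 1 point per pair of libraries. The grey band spans the template pair's SD of 1.04 on either side of 0, and 6 points lie above it and 1 below it, at -2.31 for the Hbb-b1 promoter to 3' HS-1.

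Over the 14 pairs of viewpoint and target with 2 tissues, 12 had a higher O/E in the first tissue, which was liver at the globin loci and thymus at Satb1. Of these, 6 were beyond the template pair's SD, and 1 of the 14 was lower beyond it. Expression was not measured here. By the narrower yardstick of 0.45, added after the data were seen, 10 were higher and 2 lower beyond it. The pairs are not independent, since they share libraries and several are the 2 ends of 1 contact. The count also depended on the setting. With the decay on the target's side 3 were higher beyond the SD of 1.04, all at Satb1, and 0 lower. From the Satb1 promoter that setting could hardly act, since the other side covers only 272 kb and the -470 kb site lies 446.25 kb away. Those differences went from 1.14 and 1.23 to 1.14 and 1.22, so they do not show Satb1 to be more robust than the globin loci. From the -470 kb site the difference went from 1.39 to 1.06. Over all settings applied to the 14 pairs the higher ones ran from 0, with targets reaching 10 kb to either side, to 8 with a power-law decay.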

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

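The test with the higher window values and the decay of both sides was chosen after the result was seen, and the others before. The contact between the Hbb-b1 promoter and 3' HS-1 moved in opposite directions between liver and brain depending on the end it was seen from, with a log2 O/E difference of -2.31 from the Hbb-b1 promoter and 0.27 from 3' HS-1. The difference between both directions was not tested, as each rests on 1 library per tissue, and the second value is within the template pair's SD of 1.04. The first value was at percentile 29.8 of the differences at distance-matched positions, so it was not particular to 3' HS-1. One technical explanation is that the strong HS-2 contact at a like distance on the other side raised the level expected at 3' HS-1 in liver. With the decay fitted on the target's side alone the Hbb-b1 promoter's difference became 0.60, a change in the direction that explanation requires. A decay fitted per side takes its level from that side alone, so it shrinks a deficit of the whole side whatever its cause. The 3' HS-1 side held 20.9% of the signal in liver and 53.5% in brain. This setting therefore cannot tell that explanation from a biological deficit. Without any decay the difference was still -1.28, beyond the SD. The expected level is then the library's mean, to which the HS-2 side gave 79.1% of the signal in liver and 46.5% in brain. That setting therefore cannot tell how far a raised expected level goes. The signal itself at 3' HS-1 was 0.0263 in liver and 0.0485 in brain. The decay on the target's side gave -0.14 from 3' HS-1, so the signs stayed opposite, with both values within the SD. For empty fragment ends in the liver library no test decided. The higher window values with the 1-sided decay gave 0.20, but that decay alone had already moved the value, and with the decay of both sides they gave -1.53, still beyond the SD and less than 1 SD from the middle values. No test separated these from a biological difference between liver and brain, which stays open.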

How the results depend on the processing

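A value counts as moved when it changed by more than the template pair's SD, a correlation left its interval or a count of shared maxima changed more than 1.5-fold, and as reversed when a value beyond that SD changed sign. Under other settings 7 values of tissue differences moved and 1 reversed, and of 297 values of single libraries 274 stayed, 21 moved and 2 reversed. Of 558 values at positions with the largest tissue differences 49 moved and 2 reversed, and of 828 values of maxima 45 moved and 4 reversed. Of 46 SDs 5 were counted as moved, among them the template pair's to 1.56 with the 2 kb window and 1.47 beyond 50 kb. Both lie outside its interval of 0.76 to 1.21, though each change is smaller than the template pair's SD. Of 54 values of HS elements placed by name 2 moved. Differences within the SD changed sign too, for HS-62 from HS-2 with the 1-sided (0.37) and power-law decay (0.12), and from 3' HS-1 for HS-2 with the 2 kb window (-0.55) and 1-sided decay (-0.37) and for the Hbb-b1 promoter with the 1-sided decay (-0.14). With the decay on the target's side alone, the Hbb-b1 promoter at 3' HS-1 turned to 0.60 for liver minus brain and 0.62 for liver by itself. The Satb1 promoter's difference at 51.922 Mb then turned to 0.028 for thymus minus ES cells and 0.036 for thymus minus brain, because each side got its own expected level. With a power-law decay the Hba-a1 promoter at HS-26 gave 3.12, HS-26 at the Hba-a1 promoter 2.06, the Hbb-b1 promoter at HS-2 2.89 and at 3' HS-1 -0.32, with 0.11 for liver by itself, and the Satb1 promoter at -470 kb 2.53 for thymus minus ES cells. Without a decay the last was 2.98 and the Hbb-b1 promoter at HS-62 -1.01, and 3 maxima far from their viewpoints fell below the library mean, in liver at 32.113 Mb (-0.38) from the Hba-a1 promoter and at 111.098 Mb (-1.14) from the Hbb-b1 promoter, and in ES cells at 52.323 Mb (-0.22) from the Satb1 promoter. With the 20 kb window the Oct4 promoter's NlaIII/Csp6I maximum at 35.576 Mb came to -0.000897. That window raised Spearman's rho to 0.929 for the template pair, 0.857 for liver and brain at the Hba-a1 promoter, 0.915 for the Satb1 promoter and +1.5 kb and 0.926 for the promoter and -6 kb, where the 10 kb window gave 0.909. Division by the decay lowered rho to 0.468 for the Oct4 pair, 0.655 for the Satb1 promoter and +1.5 kb, 0.693 for the promoter and -6 kb, 0.540 for +1.5 kb and -6 kb, 0.074 for thymus and ES cells and 0.080 for thymus and brain. Maxima within 5 kb were shared by 1 in the Oct4 pair, 1 between the Satb1 promoter and +1.5 kb and 0 between +1.5 kb and -6 kb. For the power-law, window, correlation and maxima changes the cause was not tested.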

Other observations

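Some Satb1 sites recurred across viewpoints and tissues. A position between 52.598 and 52.607 Mb was a maximum in 4 libraries, from the promoter, +1.5 kb and -470 kb viewpoints in thymus and from the promoter in fetal brain, with O/E from 1.92 to 5.21. A position between 52.204 and 52.213 Mb was a maximum in the same 4 libraries, with O/E from 1.56 to 3.62. The site at 52.311 to 52.319 Mb was a maximum of 3 thymus libraries, with O/E from 1.98 to 4.53, and the highest maximum of the promoter in ES cells lay beside it at 52.323 Mb with 2.40. At the alpha-globin locus 32.161 to 32.170 Mb was a maximum in 5 libraries, from both viewpoints and both tissues, with O/E from 1.04 to 1.92. A position at 32.113 to 32.114 Mb was a maximum of the Hba-a1 promoter in both liver libraries and in brain, with O/E from 1.64 to 2.36. Its relative signal in the full liver library was 0.748, below the library mean. At the beta-globin locus 111.018 to 111.024 Mb was a maximum in 3 liver libraries, from 3' HS-1, HS-2 and HS-62, with O/E from 1.68 to 3.02, and HS-2 in brain had one beside it at 111.016 Mb with 1.34. Of 84 named maxima at the alpha-globin, beta-globin and Satb1 loci, 20 lay within 10 kb of another viewpoint. The share for randomly placed positions was not computed.

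Certain positions were empty in every library of a locus. There were 12 such positions among 396 at the beta-globin locus, including 110.967 to 110.968 Mb near the Hbb-b1 promoter. There were 19 among 1296 at the Satb1 locus and 0 among 346 at the alpha-globin locus.

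The percentile test and the test with the 1/16 template library in the next paragraphs were chosen after their results had been seen, and the others before.

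In thymus the -470 kb site of Satb1 differed between neighbouring viewpoints by a log2 O/E of 2.24 from -6 kb to +1.5 kb. A flatter profile of the -6 kb library would keep the site's rank if there were no noise, yet its percentile was 25.2 points lower than from +1.5 kb. With noise a flatter profile can lose rank as well, so the percentile does not exclude it. A narrow smoothing window would let the difference vanish at 20 kb, where it was still 1.84, beyond the template pair's SD. The enzyme pair stays open too, because each viewpoint used another pair, and between 2 pairs at the Oct4 promoter the SD of log2 O/E was 0.76. All 3 libraries were of thymus, so no biological explanation was tested.

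The higher contact of the Hba-a1 promoter with HS-26 in liver came from a library with 21.2% empty positions, against 0.531% in brain. Replacing it by the 1/16 template library, with 0.796% empty positions, lowered the log2 difference from 1.29 to 0.94. That is within the template pair's SD of 1.04 and beyond the narrower yardstick of 0.45. The replacement does not settle the role of library fill, because the 1/16 library had 96 distinct values, fewer than the full library and the 267 in brain, and 43.8% of its positions held 1 value. Library fill and the tissue both stay open.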
